A study of Mus musculus with 10 samples.

How the data were processed

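RNA was measured in pools of 2 optic nerve heads from C57Bl/6 male mice, 5 pools from right eyes held at 30 mmHg for 1 h and collected 3 days later, and 5 pools from unoperated left eyes. Per the labels' protocols, total RNA was extracted with RNeasy Plus Micro kits, amplified with the Ovation system, biotin-labelled and hybridised, with 1 array per pool. The labels call the pools biological replicates and give the same replicate numbers in both groups, but do not say whether equal numbers are the same mice.

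The authors deposited 1 table of probe set intensity on a linear scale, with a value for each of 22690 probe sets on each of the 10 arrays. The values ran from 0.69 to 20168. The summarisation method, the background correction and the normalization between arrays are not given in the sources used here. The array medians were not equal, so the summarised values had not been quantile normalized. No scanner files or detection calls were used, so whether a dim probe set lay above background was not known, and the number of arrays limits the precision.

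Intensities were put on the scale log2(signal + 16). A fold change on this scale understates changes of dim genes. Of the probe sets, 64 were controls. Of the 22626 others, 20380 had 1 gene symbol in the platform annotation, 691 had several and 1555 were not in it and stay unnamed here. Entrez identifiers of 20351 of the 20380 were found in a RefSeq gene table of the mouse, and 0 symbols needed an update. For each gene the probe set with the highest mean over all 10 arrays was taken, blind to group, which left 12393 genes. No filter on dim genes was used. For the 4956 genes with several probe sets, the text says where another probe set of a gene whose fold change is given had the opposite sign.

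The 2 groups were compared with limma 3.58.1 (lmFit and eBayes, R 4.3.3), elevated pressure minus control, without covariates or blocks, and p-values were adjusted by the Benjamini-Hochberg method over all genes. A gene was called at an adjusted p under 0.05. Confidence intervals are at 95%. The 39 gene lists, covering cell types of the nerve head and of neighbouring eye tissue and responses to injury, were fixed before the data were examined, as were the tests and the rule for named genes. Of the 968 names on them 845 were measured, and each list had at least 5 measured members. Lists were tested with camera at a preset correlation of 0.01, with an estimated correlation and fry given beside it, and adjusted over the 39 lists. The score of a list on an array is the mean over its members of the log2 value minus the gene's mean over 10 arrays, and scores were compared by a two-sided exact permutation test over 252 splits. Genes were named by rule: 25 injury-response genes whatever their value, the 12 genes with the smallest p in each direction because none passed the test, and up to 4 members with the smallest p of a list. Preparation and plots used Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9.

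The gene test was checked on simulated data, 10 runs of 12393 genes with 5 and 5 independent arrays and 200 genes changed. It recovered 41%, 84.4%, 96% and 98.2% of genes changed by 0.5, 1, 1.5 and 2 on the log2 scale, with 8.2 unchanged genes called per run. When none were changed it called 0 genes per run. The set test called a simulated shift of 0.25 on the log2 scale in 10 of 10 runs. The simulation assumed arrays without shared differences in tissue content.

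The alternatives were quantile normalization, equal array medians, the mean over probe sets or all probe sets, leaving out the dimmest 25% or 50% of genes, a trended robust variance, array weights, the replicate number as a fixed or random block, scores of photoreceptors, skeletal muscle or myelin as a covariate, leaving out each array or each replicate number, a pseudocount of 1, other thresholds, other set tests, and lists without shared genes. The ratio of the 3' to the 5' Gapdh control probe set as a covariate was added after seeing the data. A gene fixed in advance whose symbol was not on a measured probe set is not reported here.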

Results

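Gene expression was measured in the optic nerve head of C57Bl/6 male mice, the site where retinal ganglion cell axons leave the eye. The pressure of the right eye had been raised to 30 mmHg for 1 h through a cannula in the anterior chamber, and the tissue was taken 3 days later. The left eye of the same animals was not operated on and served as the control. Each of the 10 arrays was hybridised with RNA from a pool of 2 nerve heads, which gave 5 arrays of elevated pressure and 5 of control tissue from 10 mice. The side of the body and the cannulation itself went with the pressure in this design, so the comparison was of operated right eyes with unoperated left eyes. The median probe set signal lay between 414 and 475 on the 10 arrays, and the number of arrays set the precision of every comparison.

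The comparison asks which genes differ in the nerve head 3 days after a brief, moderate rise of pressure. Gfap and Vim, which reactive astrocytes express strongly, had log2 fold changes near 0. Gfap, the intermediate filament protein of astrocytes, had a mean signal of 11340 ± 492 (SD, n = 5) in control and 11579 ± 726 (SD, n = 5) in elevated pressure tissue, a log2 fold change of 0.03 with a 95% confidence interval from -0.13 to 0.19. The log2 fold change of Vim, which encodes vimentin, was -0.02, with an interval from -0.16 to 0.11, and another probe set stood at 0.00. Both genes lay near the top of the signal range, which ended at 20168, and whether differences are compressed there was not tested. Among myelin genes the bright Mbp spanned 1.14-fold over the 10 arrays and the dimmer Mag 5.90-fold. The gene with the smallest p was Npr1, a receptor for natriuretic peptides, at 84.6 ± 15.0 (SD, n = 5) in control and 157 ± 29.9 (SD, n = 5) in elevated pressure tissue. Across 12393 genes, 0 differed at a limma adjusted p under 0.05, and the lowest adjusted p was 0.849.

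**Figure D1:**
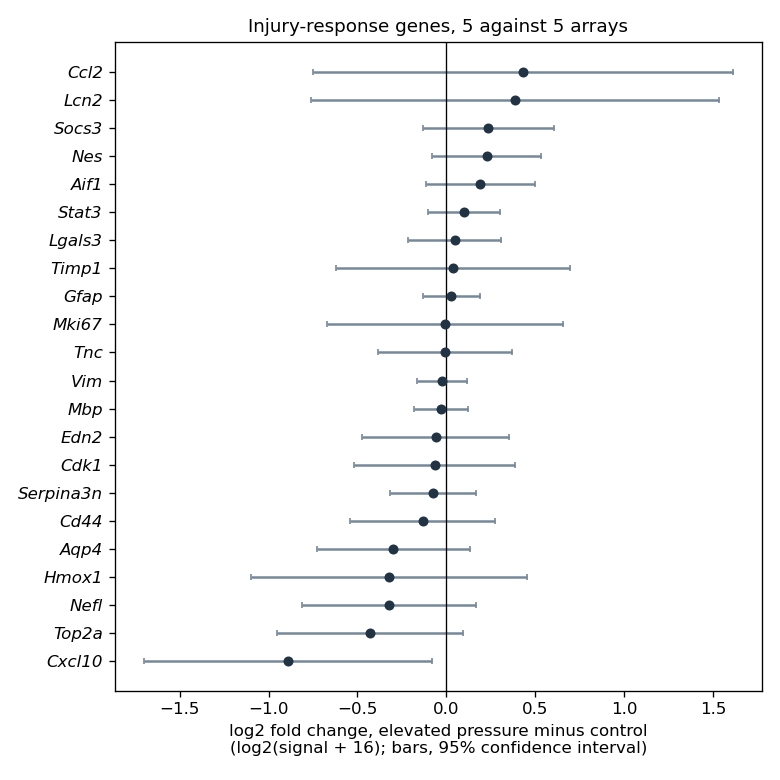
Log2 fold change (elevated pressure minus control, on log2 of signal plus 16) of the 22 measured injury-response genes fixed before the data were examined, as points with 95% confidence intervals from limma over 5 and 5 arrays. The interval of Gfap runs from -0.13 to 0.19, and that of Cxcl10, from -1.70 to -0.08, is the only one that leaves out 0.

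Of the 25 injury-response genes fixed in advance, 22 were measured and the other 3 were not analysed here. For 12 of the 22 the 95% confidence interval lay within 1.5-fold in both directions, and for 18 within 2-fold. Cxcl10, an interferon-induced chemokine, was the only one whose interval left out 0 (limma adjusted p = 0.849), with a mean signal of 4740 ± 2037 (SD, n = 5) in control and 2554 ± 1161 (SD, n = 5) in elevated pressure tissue. Its log2 fold change was -0.89 with a standard error of 0.368. Nes, which encodes the intermediate filament nestin, had a log2 fold change of 0.23 (interval -0.08 to 0.53) and the water channel gene Aqp4 one of -0.30 (interval -0.73 to 0.13). Stat3 and Socs3, a transcription factor of cytokine signalling and its feedback inhibitor, had log2 fold changes of 0.10 and 0.24. The secreted proteins Timp1 and Serpina3n stood at 0.04 and -0.07, the matrix protein gene Tnc at -0.01, the lectin gene Lgals3 at 0.05, and the adhesion receptor gene Cd44 at -0.13. Lcn2 and Ccl2 had log2 fold changes of 0.39 and 0.43, but their intervals, from -0.76 to 1.54 and from -0.75 to 1.61, left room for changes of 2-fold and more in the higher direction. The dividing-cell genes Mki67, Top2a and Cdk1 had values of -0.01, -0.43 and -0.06, the microglial gene Aif1 0.19, and the neurofilament gene Nefl, expressed by axon-bearing neurons, -0.32. Hmox1, Edn2 and the myelin gene Mbp stood at -0.32, -0.06 and -0.03. Many of these values moved by more than 1.5 times when 1 array was left out. Leaving out elevated pressure replicate 1, Hmox1 stood at -0.01, Aqp4 at -0.13, Nes at 0.11, Stat3 at 0.03 and Socs3 at 0.13, and without control replicate 1 Hmox1 at -0.11 and without control replicate 4 Socs3 at 0.14. Top2a stood at -0.27 without elevated pressure replicate 2, and Nefl at -0.17 without elevated pressure replicate 2 and -0.51 without 4. Over the 10 arrays left out in turn, Lcn2 ran from 0.09 (without elevated pressure replicate 1) to 0.81 (control replicate 1), Ccl2 from 0.05 (control replicate 2) to 0.71 (control replicate 5), Cd44 from -0.27 (elevated pressure replicate 3) to -0.04 (elevated pressure replicate 2) and Timp1 from -0.11 (elevated pressure replicate 5) to 0.32 (control replicate 5). Gfap, Tnc, Lgals3, Mki67, Cdk1 and Edn2, all near 0, changed sign. For Stat3, Top2a and Cd44 other probe sets of the gene had the opposite sign, and the 8 probe sets of Mbp ranged from -0.81 to 0.05.

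The genes with the smallest unadjusted p were taken next, 12 in each direction, none of them past the test over all genes. Among those higher after elevated pressure were Npr1 (log2 fold change 0.78, standard error 0.139) and Nos3, the endothelial nitric oxide synthase (0.40, standard error 0.105). Drc1, which encodes a part of motile cilia, had a log2 fold change of 0.57, and Insrr, a receptor related to the insulin receptor, one of 0.69. The transcription regulators Hmg20b, Lmo1 and Pgr, the progesterone receptor, had values of 0.44, 0.40 and 0.31, and Rhpn1, Pudp and Tlcd2 values of 0.50, 0.48 and 0.37. Mecom and Zgpat stood at 0.32 and 0.33, but another probe set of each had the opposite sign (-0.14 and -0.01). All 12 had every elevated pressure array above every control array. Among those lower were Serpinc1, which encodes antithrombin (-0.54), Itgam, the CD11b integrin chain of myeloid cells (-0.41), and Flt3, a growth factor receptor of blood progenitors (-0.43). The log2 fold changes of Akap3, Stil, Trim35, Casq2, Rsph6a and Wdhd1 were -0.44, -0.52, -0.42, -0.41, -0.42 and -0.60. Nek4 and Nat8f2 had values of -0.49 and -0.60, and another probe set of each lay above 0 (0.10 and 0.04). The remaining lower transcript has only a clone identifier and is counted here without a name. Several of these were dim: Itgam had mean signals of 22.9 and 13.3, Akap3 of 25.4 and 14.5, and Rsph6a of 14.1 and 6.62, near the 16 added before the log.

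**Figure D2:**
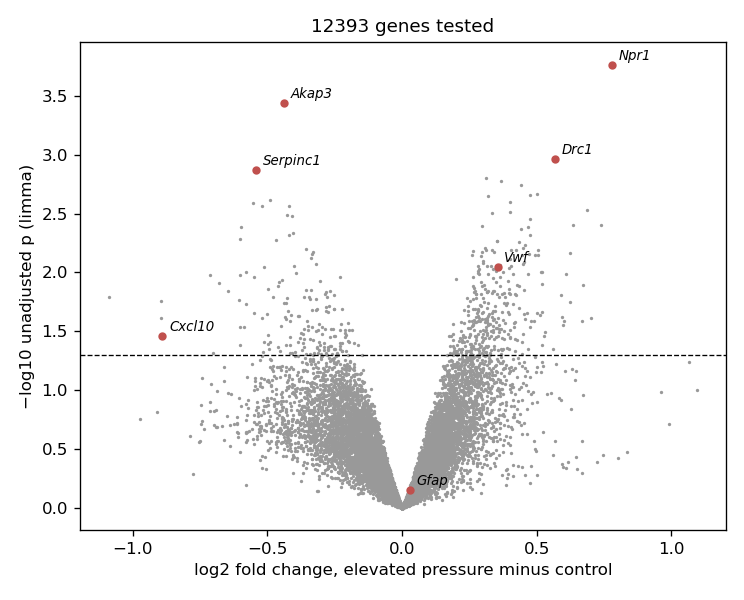
Each point is 1 of the 12393 genes, with the log2 fold change (elevated pressure minus control) on the horizontal axis and the negative log10 of the unadjusted limma p on the vertical axis, the dashed line marking 0.05. Npr1 is the highest point, at a log2 fold change of 0.78, and Gfap lies near the bottom at 0.03.

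At an unadjusted p under 0.05 there were 492 genes, 328 of them higher and 164 lower, where 5% of the genes tested would be 620. Of these 492, 14 were at least 1.5-fold higher and 15 at least 1.5-fold lower. In 78 genes the groups did not overlap, 50 of them with elevated pressure above control, where chance alone gives 98.4 genes (0.794% of them). For 95.5% of genes the 95% confidence interval lay within 2-fold. On simulated data with the same number of independent arrays and 200 genes changed at once, the limma test recovered 84.4% of genes changed 2-fold. It recovered 41% of genes changed by 0.5 on the log2 scale. Recovery when only a few genes change was not simulated.

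Genes induced by interferon had the lowest median of the 39 lists after elevated pressure. All 22 measured members had a negative log2 fold change, with a median of -0.24, among them Ifit2 (-0.49), the transcription factors Irf7 (-0.61) and Irf9 (-0.24), and the GTPase gene Gbp2 (-0.40). Genes of myelinating oligodendrocytes were lower in 16 of 18 cases (median -0.23), with Mag at -0.54, Car2 at -0.43, Tspan2 at -0.31 and Gjc3 at -0.70. Genes of cholesterol synthesis were lower in 15 of 18 cases (median -0.16), with Idi1 at -0.50, Srebf2 at -0.20, Stard4 at -0.27 and Hsd17b7 at -0.39. Extracellular matrix genes were higher in 27 of 39 cases (median 0.10), with the laminin gene Lama2 at 0.27, the collagen genes Col18a1 at 0.29 and Col5a1 at 0.21, and the proteoglycan gene Vcan in the opposite direction at -0.29. Another probe set of Col5a1 stood at -0.24. Mag, Car2, Tspan2 and Gjc3 stood at -0.22, -0.15, -0.14 and -0.29 without elevated pressure replicate 1, where Idi1 and Hsd17b7 stood at -0.21 and -0.23 and Vcan at -0.15. Without control replicate 3 Mag stood at -0.34, without elevated pressure replicate 3 Irf7 at -0.36 and Hsd17b7 at -0.60, and without control replicate 1 Irf9 at -0.10.

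These were the 4 of 39 gene lists called by the limma camera test with a preset correlation of 0.01 between genes, at adjusted p of 0.00296 for interferon, 0.0177 for myelin, 0.0186 for cholesterol and 0.0186 for matrix. None of the 4 calls held with an estimated correlation (adjusted p = 0.940 for each), where the estimated correlations between members were 0.705, 0.564, 0.620 and 0.158. By fry no list passed (lowest adjusted p 0.992). In each of the 4 lists 0 members passed the test over all genes and 0 passed when adjusted over the list alone. The score of each list per array, its mean log2 deviation, differed between groups by -0.30 for interferon, -0.25 for myelin, -0.16 for cholesterol and 0.08 for matrix, with two-sided exact permutation p of 0.357, 0.333, 0.286 and 0.222 over all splits. Over the 39 lists the lowest exact permutation p was 0.0556, for skeletal muscle (adjusted p 0.982), and the smallest p these arrays can give is 0.00794. A list alone at that smallest p could not pass after adjustment over 39 lists. The skeletal muscle members did not move together (mean pairwise correlation -0.015), so their score need not measure muscle content.

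**Figure D3:**
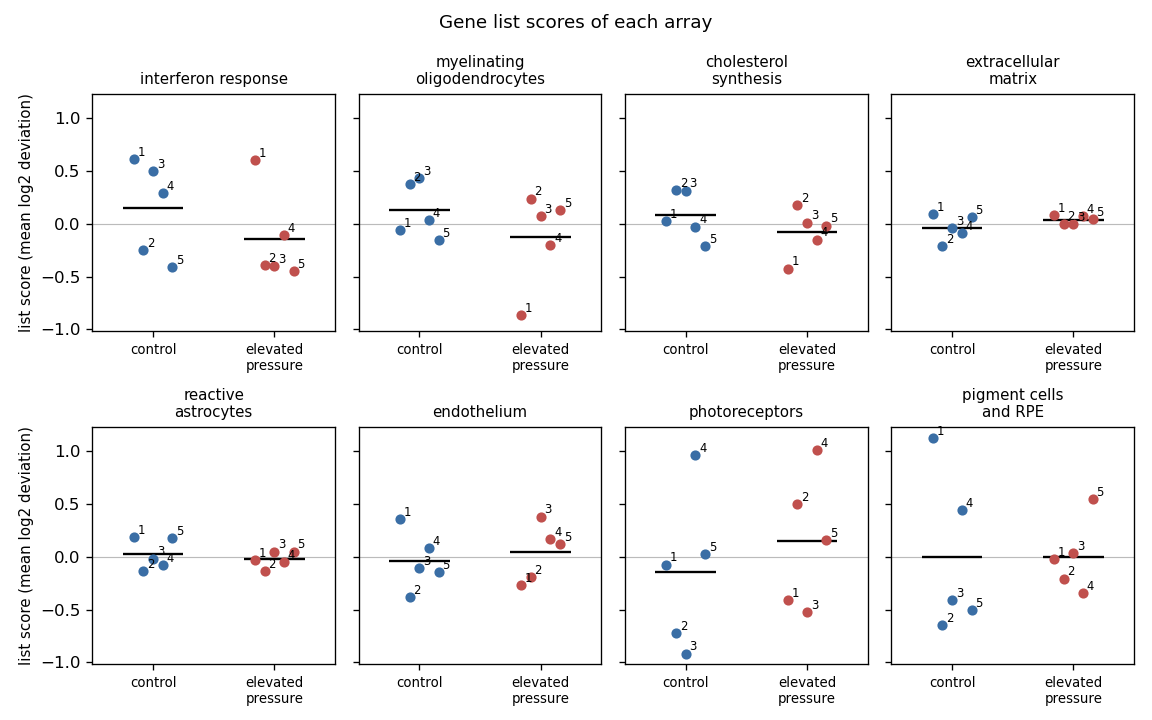
Score of 8 gene lists on each array (mean log2 deviation of the members from their mean over 10 arrays), as points numbered by replicate with a line at the group mean, for control (left) and elevated pressure (right). Elevated pressure replicate 1 has an interferon score of 0.60 among the others' -0.45 to -0.11, and a myelin score of -0.87 where the other 9 arrays lie between -0.20 and 0.43.

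The interferon score was 0.61, 0.50 and 0.29 in control replicates 1, 3 and 4 and -0.25 and -0.41 in replicates 2 and 5. In the elevated pressure group it was 0.60 in replicate 1 and between -0.45 and -0.11 in the other 4. The interferon call was lost without control replicate 3 (median -0.18, camera adjusted p 0.162), elevated pressure replicate 3 (-0.23, 0.107) or elevated pressure replicate 5 (-0.19, 0.0629), against a median of -0.24 with all arrays. Its median was -0.12 without control replicate 1 (adjusted p 0.0409), -0.41 without control replicate 5 (1.68e-06) and -0.42 without elevated pressure replicate 1 (9.72e-14). These adjusted p assume a correlation of 0.01, while interferon members had a mean pairwise correlation of 0.647 without that last array. Such small values therefore overstate the evidence. Every camera adjusted p with an array left out, here and below, rests on the preset correlation. Elevated pressure replicate 1 stood apart from the rest, with a mean correlation with the other arrays of 0.974, against 0.986 or more for each other array, and a ratio of the 3' to the 5' Gapdh control probe set of 2.07 against 1.53 to 1.73, while its ratio for actin was 2.10 against 1.65 to 2.13. Without it the median of the myelin list was -0.06 (adjusted p 0.281) and that of the cholesterol list -0.07 (adjusted p 0.195). Both calls were also lost without control replicate 2 (myelin median -0.13, adjusted p 0.146, and cholesterol median -0.10, adjusted p 0.320) and without control replicate 3 (-0.13, 0.405, and -0.09, 0.445). The same held without elevated pressure replicate 4 (-0.19, 0.0945, and -0.12, 0.139) and elevated pressure replicate 3, where the medians were no smaller (-0.28, 0.0520, and -0.17, 0.0638). The myelin median was -0.40 without elevated pressure replicate 2. The matrix call, with a median of 0.10, was lost without control replicate 2 (median 0.04, adjusted p 0.320), 3 (0.11, 0.143) or 4 (0.07, 0.102), and without elevated pressure replicate 1 (0.06, 0.0516), 2 (0.08, 0.0645) or 5 (0.11, 0.0533).

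Neither the astrocyte lists nor the microglial list was called. Of 30 measured genes of reactive astrocytes 14 were higher and 16 lower, with a median log2 fold change of -0.01 (camera adjusted p 0.682), and of 21 genes of astrocyte identity 6 were higher and 15 lower (median -0.02, adjusted p 0.682), with Cldn10 at -0.89 and the membrane protein gene Mlc1 at -0.18. Microglial and macrophage genes were lower in 15 of 21 cases (median -0.08, adjusted p 0.342), with the purinergic receptor gene P2ry12 at -0.65 and the integrin gene Itgax at 0.24. Without elevated pressure replicate 1 the median was -0.02 (adjusted p 0.761) and P2ry12 stood at -0.26, and without elevated pressure replicate 2 Itgax stood at 0.16. Among 11 genes of antigen presentation, the class II genes Cd74, H2-Aa, H2-Ab1 and H2-DMa had log2 fold changes of 0.30, 0.40, 0.30 and 0.22, while the list's median was -0.05 and its mean 0.06 (adjusted p 0.682). Cell cycle genes were lower in 25 of 40 cases (median -0.04, adjusted p 0.682), with Ttk at -0.46 and Kif20a at -0.45. Their median was -0.11 without elevated pressure replicate 4 (adjusted p 0.0549) and 0.02 without elevated pressure replicate 2 (0.846).

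Endothelial genes were not called, although 3 of 22 were higher at an unadjusted p under 0.05. Vwf, which encodes von Willebrand factor, had a mean signal of 4045 ± 482 (SD, n = 5) in control and 5170 ± 551 (SD, n = 5) in elevated pressure tissue, a log2 fold change of 0.36 with a standard error of 0.112. Robo4, Eng and Cldn5 had log2 fold changes of 0.49, 0.42 and 0.18, and the list's median was 0.06 (camera adjusted p 0.109, adjusted p = 0.940 with an estimated correlation). Without elevated pressure replicate 1 the endothelial list was called (median 0.16, adjusted p 0.00331), and it was also called without control replicate 1 (0.14, 0.000698), control replicate 4 (0.10, 0.0297) or elevated pressure replicate 2 (0.09, 0.0179). Its median was -0.01 without control replicate 2 (adjusted p 0.620), -0.02 without elevated pressure replicate 3 (0.716), 0.02 without elevated pressure replicate 4 (0.139) and 0.09 without elevated pressure replicate 5 (0.203). Of 16 mural cell genes 9 were higher (median 0.03, adjusted p 0.648), with Smtn at 0.52 and Des at 0.65 (0.41 without control replicate 2).

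Marker genes of neighbouring eye tissue varied widely between arrays of the same group. The photoreceptor score ranged from -0.92 in control replicate 3 to 1.01 in elevated pressure replicate 4, a 3.80-fold span, and its group difference of 0.29 had an exact permutation p of 0.516. Photoreceptor genes were higher in 20 of 26 cases (median 0.22, camera adjusted p 0.130, adjusted p = 0.940 with an estimated correlation), and the call appeared without elevated pressure replicate 1 (median 0.34, adjusted p 0.00758), elevated pressure replicate 3 (0.37, 0.0409) or control replicate 4 (0.44, 3.23e-05). The median was 0.07 without elevated pressure replicate 4 (adjusted p 0.613), 0.08 without control replicate 3 (0.761) and 0.12 without control replicate 2 (0.433). The score of pigment cells and retinal pigment epithelium ranged from -0.65 in control replicate 2 to 1.12 in control replicate 1, and its group difference was 0.00 (median 0.03, camera adjusted p 0.960, exact permutation p 1). Without control replicate 1 the pigment list was called as higher (median 0.27, adjusted p 0.0267), while its median was -0.19, -0.08 and -0.10 without control replicates 2, 3 and 5 and -0.09 without elevated pressure replicate 5. With all arrays and an estimated correlation its adjusted p was 0.987.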

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

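Tests of the interferon score against chance, of both lists without elevated pressure replicate 1, of pigment against photoreceptor scores and of the count of genes over splits were chosen after the results were seen. The real split of the 10 arrays had 0 genes at a limma adjusted p under 0.05, a count that all 100 splits drawn had to reach, so it says nothing about chance, and the highest other count was 1. At an unadjusted p under 0.05 it had 492 genes, against a median of 484 over the others, and 49 of 100 splits gave as many. For lists called by camera with a preset correlation, 86 of 100 splits gave 4 or more, with a median of 7 and a highest of 22 over the others, so chance could not be excluded. The split with 22, of control replicates 1, 3 and 5 with elevated pressure replicates 1 and 5 against the rest, called several times the real count. It was picked as the highest of those drawn, and whether these arrays share anything was not tested.

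The interferon list was lower after elevated pressure in all 22 measured members. Differences between arrays unrelated to pressure are a candidate explanation, since the score spanned 1.02 among the control arrays against a group difference of -0.30, with an exact permutation p of 0.357. The blood leukocyte list gave no sign of a lower leukocyte content: 7 of 12 members were higher, with a median of 0.02. Its score differed by -0.02 between groups (exact permutation p 0.960), although it spanned 1.03 among the control arrays. Over only 10 arrays with groups centred, its relation to the interferon score could not be settled. Spearman's rho was 0.261 (permutation p 0.469, adjusted 0.562) and r 0.231 (permutation p 0.514, adjusted 0.514). Without elevated pressure replicate 3 and control replicate 2, r was -0.09. Whether a single interferon-rich control array accounts for the shift was not settled by the test fixed beforehand, which left out control arrays in turn. Scores were 0.61, 0.50 and 0.29 in control replicates 1, 3 and 4, against -0.25 and -0.41 in replicates 2 and 5, so more than 1 control array was high. The size of the shift and the call still depended on single arrays. Without control replicate 1, the highest, the median moved from -0.24 to -0.12 with the call kept (camera adjusted p 0.0409). Without control replicate 3 it was -0.18 with the call lost (0.162). An effect of the pressure, or of the operation that came with it, was not tested separately and stays open.

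The myelin and cholesterol lists were lower after elevated pressure, and elevated pressure replicate 1 may account for both calls, since without it the camera adjusted p was 0.281 for myelin (median -0.06) and 0.195 for cholesterol (median -0.07), although other arrays left out also ended these calls. The cholesterol call may follow oligodendrocyte content: with the myelin score as a covariate its median moved from -0.16 to -0.01 (camera adjusted p 0.853). That call was also lost with the photoreceptor score, the skeletal muscle score or the Gapdh ratio as a covariate. Its loss was therefore not particular to the myelin score. In replicate 1 the median log2 deviation of myelin members from the mean of the other 9 arrays was -1.09. Of 10000 lists matched on mean expression 0 were as low (lowest -0.39), which argues only against an even loss of RNA over transcripts of this brightness. Those lists held genes drawn singly, while myelin members moved together (estimated correlation 0.564), so an uneven loss stays open. Other lists deviated there too, with immediate early genes at -0.54, photoreceptors at -0.53 and interferon genes at 0.54. With the Gapdh ratio as a covariate the myelin median was 0.0434. A loss specific to the myelin transcripts was not tested, and that array had the highest 3-to-5 ratio of Gapdh at 2.07 but not of actin (2.10, against 2.13 in elevated pressure replicate 4). Less myelinated nerve in that pool cannot be told apart from such a loss, because 14 of 18 members being lower there than in each of the other 9 arrays restates the pattern, in an array that was the lowest in 3531 of 12393 genes, and an effect of the pressure on myelin was not tested separately and stays open.

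The photoreceptor score differed between arrays of the same group by up to 1.88 in control and 1.54 in elevated pressure tissue. Retinal tissue carried into some pools is a candidate explanation, since the members had a mean pairwise correlation of 0.519 with groups centred, against a highest of 0.149 over 200 random lists of the same size. Interferon members reached 0.705 and cholesterol members 0.620, so members moving together do not by themselves single out carried-in tissue. Whether other eye tissue came with it cannot be told apart from separate sources, because over only 10 arrays the pigment and photoreceptor scores had Spearman's rho of 0.2 (permutation p 0.582, adjusted 0.582) and r of 0.247 (permutation p 0.491, adjusted 0.514), or r of 0.321 without replicate 4 of both groups. For inner retina and photoreceptors rho was 0.491 (permutation p 0.154, adjusted 0.231) and r 0.575 (permutation p 0.0830, adjusted 0.125), or r 0.299 without the same arrays. No biological explanation was tested, as high and low arrays occurred in both groups.

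In a group of 5 arrays the highest or lowest value was taken as far from the others when its gap to the next exceeded 0.71 of the range, which chance does in about 1 of 20 groups. Of 274 groups tested, 20 met this against 13.7 expected, and 8 of the 20 were elevated pressure replicate 1. Genes chosen after their values were seen, among them Mx1, Adipoq and Car3, were included. Some genes are also members of the lists tested. The 2 counts are therefore not a fair comparison, and an excess over chance cannot be read from them. In that array the standard deviation of log2 deviations was 0.460 (others of its group 0.212 to 0.274) and the mean correlation with the other arrays 0.974 (0.987 to 0.989). It was also the highest of its group in the heat shock score at 0.16 (-0.08 to -0.03) and in log2 Mx1 at 9.59 (6.51 to 7.28), and the lowest in P2ry12 at 6.84 (8.63 or more), Nek4 at 7.79 (8.20 to 8.37), Mlc1 at 13.21 (13.41 to 13.48) and Casq1 at 6.97 (7.38 to 7.52). Elevated pressure replicate 2 was the highest in the fat score at 0.56 (-0.13 to -0.09), in Adipoq at 7.58 (4.70 to 5.06), in Car3 at 10.22 (6.97 to 7.88) and in Itgax at 8.21 (7.74 to 7.83). Casq2 was highest in elevated pressure replicate 3 at 9.19 (8.97 to 9.03), and Vim in replicate 4 at 14.03 (13.93 to 13.95). Among control arrays, replicate 1 was the highest in the heat shock score at 0.27 (-0.11 to -0.02) and Hmox1 at 8.67 (7.46 to 7.73), and replicate 2 the lowest in Vwf at 11.65 (12.01 to 12.09) and Trib3 at 5.99 (7.14 to 7.41). Timp1 was highest in control replicate 5 at 12.23 (10.62 to 10.93), and Adipoq in control replicate 4 at 5.99 (4.86 to 5.14).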

How the results depend on the processing

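The ratio of Gapdh probe sets as a covariate was chosen after seeing the data, and all other settings before. The count of 0 genes at a limma adjusted p under 0.05 stood in each of 36 alternatives, including adjusted p under 0.1 and each array left out, and 29 genes passed at an unadjusted p under 0.05 with at least 1.5-fold change. At an unadjusted p under 0.05 the count was 492, and it ranged from 220 without the dimmest 50% of genes, where fewer genes were tested, to 1044 without elevated pressure replicate 3. It was 1004 over all probe sets, where more were tested, 304 with the Gapdh ratio and 306 with the skeletal muscle score as covariate. The share of higher genes was 66.7% and ranged from 52.3% without both arrays numbered 4 to 72% under equal medians, with 52.5% over all probe sets, 53.3% with the skeletal muscle score and 55.2% without elevated pressure replicate 4. The 4 called lists became 9 with the skeletal muscle score as a covariate, 1 with the photoreceptor score, 1 with the myelin score, 0 with an estimated correlation and 0 by fry. The cause was not tested, except that an estimated correlation allows for members moving together. The skeletal muscle score spanned only 1.14-fold over the arrays and its members did not move together (mean pairwise correlation -0.015). The 9 calls with it therefore cannot be read as an effect of muscle content. Leaving out single arrays or both arrays of a replicate number gave from 0 to 7 lists, with 0 without control replicate 3 and 7 without both arrays numbered 1, and up to 8 when a replicate block was added. In all, 22 of the alternatives, single arrays left out included, gave a count within 1.5 times of 4. The myelin list's median turned to 0.0434 with the Gapdh ratio as covariate, a ratio that was highest in elevated pressure replicate 1, and the cause was not tested. The interferon list was called in 30 of 38 settings, the myelin and cholesterol lists in 22 each the matrix list in 21, and the endothelial and photoreceptor lists in 12 each, among them array weights and the fixed replicate block. The list scores gave 0 calls in each of 13 alternatives, of which the paired sign-flip test could not have called any with 5 pairs. In the others a list alone at the smallest possible exact permutation p, 0.00794, could not have passed after adjustment over 39 lists. These counts of 0 therefore say little about a shift of single lists. The arrays were treated as sharing only a number, and pairing was not excluded: same-numbered arrays had correlations of deviations of -0.02, 0.21, -0.08, 0.18 and -0.06, and 4 of 10 arrays correlated best with their own number. With the replicate block as a fixed term 0 genes and 6 lists were called, the 4 and these 2, and with a random block 0 genes and 4 lists. Signal over background is not known for these arrays, so dim genes could not be judged.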

Other observations

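Other injury responses showed single genes with larger fold changes, and none of these lists was called with all 10 arrays and no covariate. With the skeletal muscle score as a covariate the JAK-STAT3 and matrix remodelling lists were called as higher. That score need not measure muscle content, since its members had a mean pairwise correlation of -0.015. The Gapdh ratio as a covariate gave calls of immediate early genes as higher and heat shock genes as lower. Trib3, a gene of the unfolded protein and amino acid response, had a log2 fold change of 0.70 (standard error 0.268, limma adjusted p 0.849, and 0.44 without control replicate 2), while 13 of the 25 genes of its list were higher and 12 lower (median 0.01, camera adjusted p 0.832). None of the genes named here passed the limma adjusted threshold. The immediate early gene Junb stood at 0.45 and the kinase gene Jak1 at -0.36 (-0.22 without elevated pressure replicate 1, and another probe set of Jak1 at 0.27), with medians of 0.00 for 20 immediate early genes and 0.04 for 17 genes of the JAK-STAT3 and gp130 response (both adjusted p 0.682). Without elevated pressure replicate 1 the immediate early list was called as higher (median 0.12, camera adjusted p 0.0228), while without elevated pressure replicate 3 its median was -0.08 (adjusted p 0.732) and with an estimated correlation over all arrays its adjusted p was 0.940. Tgfb1 stood at 0.45, and its lists of TGF-beta response and of cytokines and chemokines had medians of -0.04 (adjusted p 0.832) and 0.01 (adjusted p 0.763). The gelatinase gene Mmp2 stood at 0.61 in a list of 28 remodelling enzymes and inhibitors with a median of 0.01 (adjusted p 0.682). Genes of hypoxia and glycolysis were lower in 19 of 26 cases (median -0.04, adjusted p 0.239), and p53 response genes in 11 of 15 (median -0.09, adjusted p 0.648). Medians of heat shock, oxidative stress, complement, phagocytosis, actin, respiratory chain and ribosomal genes were -0.01, -0.02, 0.01, -0.05, -0.02, 0.00 and -0.01, with the lowest adjusted p among these lists at 0.682.

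Among cell types, genes of neurons and axons were lower in 16 of 25 cases (median -0.06, adjusted p 0.682), with the growth-cone gene Gap43 at -0.44. Ngfr, the p75 neurotrophin receptor, stood at 0.27 (another probe set at -0.0042), in lists of 9 peripheral nerve genes (median -0.04, adjusted p 0.682) and 26 trophic factors and receptors (median -0.03, adjusted p 0.832). Oligodendrocyte precursor genes had a median of -0.17 (adjusted p 0.682), with Olig2 at -0.49. Without elevated pressure replicate 1 the medians of the neuron and precursor lists were 0.00 and -0.02 (both adjusted p 0.941), with Gap43 at -0.18 and Olig2 at -0.25. The neuron score was lowest in elevated pressure replicate 1 (-0.43) and highest in elevated pressure replicate 4 (0.50). Leaving out replicate 4 therefore makes the group difference of that score larger. The next highest neuron scores were in control replicates 4 (0.39) and 1 (0.30). The inner retina score was highest in the same arrays, at 0.43 in elevated pressure replicate 4, 0.18 in control replicate 4 and 0.48 in control replicate 1. The relation of the neuron and inner retina scores was not tested, so retinal tissue in the pools cannot be told apart from a change in axons. Skeletal muscle genes were higher in 15 of 22 cases (median 0.07, adjusted p 0.171), with Tnnc2 at 0.37 and Casq1 at -0.33. The medians of blood leukocyte, red blood cell, fibroblast, inner retina, lens and fat lists were 0.02, -0.15, 0.01, -0.04, -0.07 and 0.02, each with an adjusted p of 0.682, and the red blood cell median was 0.00 without elevated pressure replicate 1. In 7 lists the median, the mean and the test differed in sign: blood leukocytes, cytokines, immediate early genes, antigen presentation, TGF-beta response, respiratory chain and trophic factors.

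Of genes chosen after their values were seen, the photoreceptor genes Pdc and Sag spanned 21.4-fold and 14.9-fold between the lowest and highest array, the pigment epithelium gene Rpe65 21.3-fold, and the interferon-induced gene Mx1 8.42-fold. The fat genes Car3 and Adipoq spanned 9.50-fold and 7.37-fold, with the highest value of both in elevated pressure replicate 2.

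Over the 10 arrays with groups centred, the myelin and cholesterol scores, which share 0 genes, had Pearson's r of 0.935 (permutation p 4.0e-05, adjusted 0.00012) and Spearman's rho of 0.903 (permutation p 0.00071, adjusted 0.00213). Without elevated pressure replicate 1 and control replicate 5, the arrays farthest from the median myelin score, r was 0.915. The myelin and precursor scores had r of 0.989 (permutation p 1e-05, the smallest that 100000 resamples can give, adjusted 6e-05) and rho of 0.976 (permutation p 3e-05, adjusted 0.00018), and r of 0.962 without the same 2 arrays. The precursor members themselves had a mean pairwise correlation of only 0.121. In elevated pressure replicate 1, 7 of 11 were lower and 3 higher than in each of the other 9 arrays. The relation of the scores therefore does not hold for every precursor gene. Endothelial and mural scores had r of 0.645 (permutation p 0.0445, adjusted 0.0890) and rho of 0.612 (permutation p 0.0664, adjusted 0.133), and r of 0.372 without control replicates 1 and 2. Leaving out the arrays farthest from the median also narrows the range of the scores. Whether that relation rests on those arrays therefore cannot be told. In all, 6 relations were computed.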
